A study of Mus musculus with 23 samples.

How the data were processed

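Total RNA was measured on 23 Agilent SurePrint G3 mouse arrays of design 8x60K, in 1 colour. Per the labels, RNA was extracted with miRNeasy columns and labelled with Cy3 by low-input quick amplification. Myoblasts were grown on collagen in growth medium, and myotubes were made on Matrigel in differentiation medium for 1, 2 or 4 days. Stem cell lines were of 129 substrains, myoblasts and myotubes of C57BL/6J mice. Samples were grouped by their labels into stem cells, passage 0 myoblasts, proliferating myoblasts at passages 8 to 10, myotubes of days 1, 2 and 4, and quadriceps, with n = 3 in each. The 2 arrays of stem cell line E14tg2 were averaged to 1 sample. The single NOD/ShiLtj muscle sample had no replicate and was left out of the main fit.

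Per the file headers, Agilent's Feature Extraction made the processed signal intensity of each spot by background subtraction, spatial detrending and multiplicative detrending. The mean and background signals in the same files, as deposited, are raw intensities, and the flags for spots above background, saturated or out of line are 0 or 1. The authors also deposited a series matrix of log2 values, whose columns all have a median of 6.72 and differ by at most 0.01 once sorted. Such columns arise from quantile normalization, but the method is not stated. No array had saturated spots except the NOD array, which had 1.

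Of 62976 spots per array 59305 were not controls, and these held 55681 probes. Genes were named through the RefSeq table by accession for 26582 probes, by symbol for 2602 and by synonym for 492, while 26005 kept the name in the file. This gave 36095 gene names, of which 21983 are known to RefSeq and 10402 had more than 1 probe. Probe positions are those in the files, on mouse build mm9. Col6a3, Hbb-b1 and Rian of the fixed lists were not on the array.

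The log2 of the processed signal was taken and each array's 75th percentile over the spots that were not controls was subtracted. Spots called out of line by the scanner software were left out, spots of a probe were averaged, and each gene was represented by its brightest probe over all arrays. A limma model with a mean for each of the 7 groups was fitted to 21 samples, leaving 14 residual degrees of freedom, with empirical Bayes moderation of the variances. A gene was tested where it was well above background on every sample of at least 1 of the 2 groups. It was called at a Benjamini-Hochberg adjusted p under 0.05 and a fold of at least 2. There were 9 comparisons, of which 4 were the main ones. The p-values measure the spread between these samples, since the labels do not say whether the numbers mark animals or separate cultures.

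Where no sample of a group was above background, the fold was computed against a floor. On each array the floor was the higher of the lowest signal among probes well above background and the probe's own signal, and the fold is printed as a lower bound. List medians are given with such genes at their bound where this changes them.

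A set of 34 gene lists was written before the data were examined, as were the samples' groups, the alternatives and the rule for naming genes. Lists were tested with camera in the main comparisons at a preset correlation of 0.01 and with an estimated correlation, in 133 pairs of list and comparison with at least 3 tested genes, and adjusted over those pairs. Too few genes were tested in 3 further pairs. With the preset correlation 60 pairs had an adjusted p under 0.05, and with the estimated correlation 1. The named genes were the 6 higher and 6 lower called genes with the largest fold that were measured in both groups without overlap, the 2 called members of each list with the largest fold, and a fixed set of regulators, myosins and DNA methylation genes. Genes of the second and the third kind are printed where they belong to a group described.

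The arrays came from 3 slides of 8, 8 and 7 arrays scanned on 1 day, and, with the repeat array of E14tg2 left out, each slide held 1 sample of each of the 7 groups. The slide was fitted as a block, and list medians were taken within slides, without that array. Titles of proliferating myoblasts and of myotubes share culture numbers. After removal of group means, samples with the same number correlated across genes at r from -0.047 to 0.625 over the 6 pairs of these groups. All were over 0.1 only between proliferating myoblasts and day 2 and between days 1 and 4. Genes are not independent replicates. A block by replicate number was an alternative. That number stands for the culture number only among proliferating myoblasts and myotubes. Elsewhere the block joins samples with different labels. In proliferating against passage 0 myoblasts it also parts the only culture number found in both, that of passage 0 replicate 1 and proliferating replicate 2, so it is no pairing of cultures there.

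Alternatives were normexp background correction with an offset of 50, quantile normalization, the authors' values, no filter on dim probes, a filter in both groups, spots called out of line kept, the mean of a gene's probes, a slide block, a replicate block, a fit to the 2 groups alone, an intensity trend in the variances, limma's treat at 1.5-fold, no minimum fold, the repeat array of E14tg2 left out, the NOD muscle sample added to quadriceps, and leaving out each sample in turn. Leaving out both of the dimmest arrays, and the list tests without proliferating myoblast replicate 1, were added after the data were seen. The fit was tested on simulated data with known folds in 200 genes. At true folds of 1.5, 2, 4 and 8 it called 0, 3, 32 and 35 of 50 genes, and the median fitted folds were 1.57, 2.05, 3.83 and 7.59. The number of arrays limits the precision. Tools were R 4.3.3 with limma 3.58.1 and the data.table package, version 1.17.8, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.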

Results

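Gene expression was measured on 23 one-colour Agilent mouse arrays that follow the skeletal muscle lineage from pluripotent cells to adult muscle. The 7 groups compared hold 3 samples each: embryonic stem cells, primary myoblasts at passage 0, primary myoblasts proliferating at passages 8 to 10, myotubes after 1, 2 and 4 days in differentiation medium, and quadriceps muscle. The stem cell lines were cGR8, RD1 and E14tg2, the last on 2 arrays that were averaged. A single skeletal muscle sample from a NOD/ShiLtj mouse entered only an alternative fit of the quadriceps comparison. Between 39.1% and 60.1% of the spots on an array were well above background. The 75th percentile of the processed signal was 87.7 intensity units on the array of proliferating myoblast replicate 1 and lay between 208 and 765 on every other array. The number of arrays limits the precision. Levels below are log2 signal relative to the array's 75th percentile, as mean ± SD with n = 3, and adjusted p for single genes are from limma's moderated test. Where no sample of a group was above background, the fold is a lower bound. Gene lists fixed before the data were examined were tested with camera, first with a preset correlation between genes and then with an estimated correlation. Counts of a list adjusted over the list alone are given where they differ from those adjusted over all genes tested.

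The first 2 principal components held 37.6% and 25.5% of the variance of 23361 genes. Across genes, which are not independent replicates, proliferating myoblast replicate 1 correlated with the other two samples of its group at r = 0.902 and 0.877, against 0.969 between those. The median SD across genes was 0.739 in that group and 0.288 in passage 0 myoblasts. The main fit takes a single spread per gene over the 7 groups, so its p-values for comparisons with proliferating myoblasts may be too small. The median log2 change over all genes tested was -0.264 for passage 0 myoblasts against stem cells, 0.141 for proliferating against passage 0 myoblasts and 0.128 for day 2 against day 1 myotubes, and changes in these comparisons are to be read against those shifts.

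**Figure D1:**
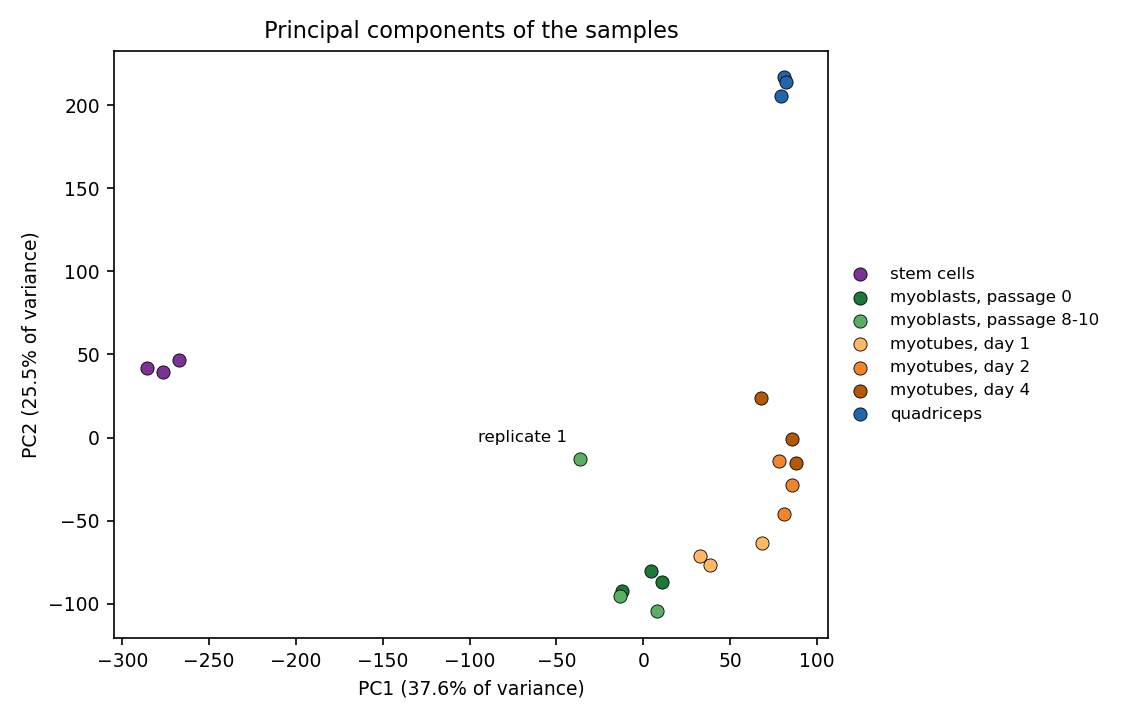
Principal components 1 (37.6% of the variance) and 2 (25.5%) of the log2 values of 23361 genes in the 7 groups, with 1 point per sample coloured by group. Replicate 1 of the proliferating myoblasts lies apart from the other two samples of its group, which lie beside the passage 0 myoblasts.

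Proliferating myoblasts, like passage 0 ones, differ from stem cells in strain and lineage, which cannot be separated. Myod1, the myogenic determination factor, stood at 6.21 ± 0.24 in myoblasts and was above background in no stem cell sample (at least 2729-fold, adjusted p = 3.4e-13). Myog, which drives terminal differentiation, was at least 1617-fold higher at 5.41 ± 1.05 (adjusted p = 4.4e-11), and the satellite cell factor Pax7 at least 213-fold higher at 2.72 ± 1.13 (adjusted p = 1.6e-10). The core pluripotency factor Pou5f1 fell from 5.95 ± 0.53 to -3.53 ± 2.58 (710-fold, adjusted p = 1.6e-07), and Sox2 from 3.49 ± 0.03 to below background (at least 150-fold, adjusted p = 1.4e-09). Limma called 3389 genes higher and 4247 lower of 21168 tested, and 3482 and 4419 with the slide as a block. Among genes called, measured on every sample of both groups and without overlap between them, the largest folds upward were those of Actc1, cardiac actin of the early sarcomere (1454-fold, adjusted p = 8.2e-09), the imprinted RNA H19 (691-fold), Tnnc1 (530-fold), Ankrd1 (448-fold), the sarcoglycan gene Sgca (362-fold) and Camk1g (355-fold). Among such genes the largest downward were those of Tdh, threonine dehydrogenase (1642-fold, adjusted p = 7.3e-10), Rex2 (547-fold), Esrrb (305-fold), Utf1 (237-fold), Apoe (133-fold) and Rasgrp2 (118-fold). Requiring signal well above background in both groups left 1783 lower calls and raised the share of calls that were higher from 44.4% to 59.6%.

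Among myogenic transcription factors 9 of 13 rose and 1 fell, with 10 and 1 adjusted over the list alone. Their median log2 change was 4.44, and 3.90 with lower bounds (adjusted p = 3.3e-06, adjusted p = 0.016 with an estimated correlation), with medians of 3.19, 5.00 and 3.44 on slides 1, 2 and 3. Myf6 was at least 7.29-fold higher (adjusted p = 0.016), a call lost with normexp background correction (adjusted p = 0.16), with the authors' values (adjusted p = 0.3) and without proliferating myoblast replicate 1 (adjusted p = 0.073) or stem cell replicate 2 (adjusted p = 0.054). Over all alternatives its adjusted p ran from 0.0048 to 0.3. The only probe for Myf5, on chromosome 10 at 106919974 to 106920033 of build mm9, was above background in no sample of the 7 groups, so Myf5 has no fold in any comparison. Satellite cell markers went mostly upward: 10 of 16 rose and 2 fell, median log2 change 3.42 (adjusted p = 7.2e-05, adjusted p = 0.14 with an estimated correlation). Examples were the adhesion molecules Vcam1 (1028-fold, adjusted p = 5.3e-11) and Cdh15 (244-fold, adjusted p = 6.3e-11).

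Of the pluripotency genes 28 of 31 fell and 1 rose. The median log2 change was -7.89, -7.21 with lower bounds, and -6.13, -8.21 and -8.36 on slides 1, 2 and 3 (adjusted p = 5.4e-20, adjusted p = 0.074 with an estimated correlation). Dppa5a fell from 9.0 ± 0.10 to -4.69 ± 0.61 (13189-fold, adjusted p = 2.8e-11) and Zfp42 was at least 1056-fold lower (adjusted p = 2.3e-09). The gene that rose was Nanog, whose 2 probes on chromosome 6 gave opposite results. The brighter probe, at 122663676 to 122663735, was 5.74-fold higher in myoblasts (adjusted p = 0.0022), and the other, at 122664590 to 122664649, stood at 6.07 ± 0.50 in stem cells and was at least 899-fold lower in myoblasts (adjusted p = 5e-11). With the mean of both probes Nanog changed by -4.67. Germline genes fell in 16 of 19 cases and rose in 0 (0 higher and 17 lower adjusted over the list alone), with a median log2 change of -4.82, -4.15 with lower bounds (adjusted p = 1.2e-09, adjusted p = 0.2 with an estimated correlation). Tex19.1 was at least 304-fold lower (adjusted p = 6.9e-10).

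Enzymes of DNA methylation divided. Among writers and readers 3 of 13 rose and 3 fell, and the list as a whole did not pass (adjusted p = 0.5). The de novo methyltransferase gene Dnmt3b fell from 5.34 ± 0.68 to -0.86 ± 0.51 (73.6-fold, adjusted p = 1.3e-10) and its cofactor Dnmt3l from 6.15 ± 0.68 to -3.70 ± 1.40 (923-fold, adjusted p = 3.7e-10). The maintenance methyltransferase Dnmt1 was at 1.41 ± 0.60 against 1.87 ± 0.26 (adjusted p = 0.26), its partner Uhrf1 at 4.40 ± 0.40 against 5.26 ± 0.12 (adjusted p = 0.29) and Dnmt3a at -0.68 ± 0.96 against 0.09 ± 0.14 (adjusted p = 0.18). In demethylation and base excision repair 4 of 23 rose and 9 fell, with a median of 0.28, a mean of -0.72 and a downward test that did not pass (adjusted p = 0.29). The methylcytosine dioxygenase Tet1 fell from 3.42 ± 0.10 to -1.97 ± 0.20 (41.8-fold, adjusted p = 4.2e-09) on all 3 of its probes, Tet2 from 2.44 ± 0.77 to -1.73 ± 2.03 (18-fold, adjusted p = 0.0001), the glycosylase Tdg from 0.90 ± 0.19 to -0.87 ± 0.33 (3.42-fold, adjusted p = 0.0001) and Neil2 from 1.37 ± 0.16 to -4.93 ± 1.35 (79.2-fold, adjusted p = 7.2e-08). Tet3 was at -0.82 ± 0.93 against -1.27 ± 0.16 (adjusted p = 0.34, and from 0.018 to 0.89 over the alternatives). The muscle-restricted deaminase family member Apobec2 rose from -4.04 ± 0.74 to -0.27 ± 0.67 (13.6-fold, adjusted p = 6.5e-07).

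Genes of the contractile apparatus were higher in the myoblasts although these were in growth medium. In the embryonic and neonatal sarcomere list 14 of 15 rose and 0 fell, with a median log2 change of 8.39 and 9.09, 7.41 and 8.73 on slides 1, 2 and 3 (adjusted p = 7.2e-14, adjusted p = 0.074 with an estimated correlation). Chrna1, an acetylcholine receptor subunit of that list, was at least 8124-fold higher (adjusted p = 5.0e-14), the light chain Myl1 at least 3489-fold (adjusted p = 3.7e-11), the embryonic myosin Myh3 56.2-fold (adjusted p = 8.3e-06) and the neonatal myosin Myh8 103-fold (adjusted p = 4.0e-09). Adult fast fibre genes followed: 13 of 18 rose and 1 fell, median 4.17 (adjusted p = 2.3e-08, adjusted p = 0.25 with an estimated correlation). Myh1 was at least 732-fold higher (adjusted p = 4.4e-11), the creatine kinase Ckm at least 21.1-fold (adjusted p = 0.00036), and Myh4 stood at -1.91 ± 1.10 against -2.63 ± 0.76 (adjusted p = 0.46). Of the slow fibre genes 11 of 15 rose and 0 fell, median 4.31 (adjusted p = 0.00022, adjusted p = 0.47 with an estimated correlation). Tnni1 was 335-fold higher (adjusted p = 3.4e-05) and Myh7 38.1-fold (adjusted p = 0.032), the latter call lost on leaving out any stem cell sample or myoblast replicate 1 or 2 (adjusted p from 0.068 to 0.075, and from 0.0002 to 0.075 over all alternatives).

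The supporting machinery of the fibre moved with it. For sarcomere scaffold and Z disc genes 27 of 30 rose and 0 fell, median 4.65, 4.39 with lower bounds (adjusted p = 1.3e-15, adjusted p = 0.13 with an estimated correlation). Examples were Tcap (311-fold) and Csrp3 (at least 172-fold). Of excitation contraction coupling genes 17 of 21 rose and 1 fell, with 18 and 1 adjusted over the list alone, median 4.19 (adjusted p = 2.3e-11, adjusted p = 0.13 with an estimated correlation). Examples were the caveolin Cav3 (at least 930-fold, adjusted p = 4.5e-11) and Sln (at least 166-fold, adjusted p = 7.0e-06). Of neuromuscular junction genes 12 of 16 rose and 2 fell, median 3.26 (adjusted p = 1.2e-07, adjusted p = 0.1 with an estimated correlation). Chrnd was 1151-fold higher (adjusted p = 1.9e-11). In the myokine and growth regulator list 13 of 15 rose and 0 fell, with 14 and 0 adjusted over the list alone, median 3.53, 3.48 with lower bounds (adjusted p = 5.2e-08, adjusted p = 0.051 with an estimated correlation). Igfbp5 was 255-fold higher. Hox genes, which set positional identity, rose in 15 of 19 cases and fell in 0 (16 higher and 0 lower adjusted over the list alone), median 4.46 (adjusted p = 6.3e-08, adjusted p = 0.079 with an estimated correlation), with Hoxa11 at least 186-fold and Hoxc9 at least 123-fold higher. In the fusion list 8 of 22 rose and 5 fell (adjusted p = 0.11), the fusogen Mymk being 108-fold higher at 4.04 ± 1.26 (adjusted p = 4.0e-08).

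Proliferation genes were somewhat lower in myoblasts. In the cell cycle and DNA replication list 0 of 44 rose and 15 fell, with 0 and 11 adjusted over the list alone, with a median log2 change of -1.01 (adjusted p = 0.0032, adjusted p = 0.67 with an estimated correlation), and 8 fell without proliferating myoblast replicate 1. Mybl2 was 11.7-fold lower (adjusted p = 4.8e-06) and Kif11 4.97-fold (adjusted p = 0.014, 0.083 without that replicate and from 0.00044 to 0.092 over the alternatives), while Mki67 was at 4.05 ± 1.58 against 5.04 ± 0.09 (adjusted p = 0.41). Cell cycle exit genes went upward: 8 of 19 rose and 1 fell, median 0.82 (adjusted p = 0.0049, adjusted p = 0.25 with an estimated correlation). Examples were the inhibitors Cdkn2c (79.3-fold) and Cdkn2b (21.6-fold). For energy metabolism, 9 of 25 rose and 4 fell in glycolysis and glycogen (adjusted p = 0.028, adjusted p = 0.64 with an estimated correlation), a call lost with normexp (adjusted p = 0.06), without a filter (adjusted p = 0.13) and without proliferating myoblast replicate 1 (adjusted p = 0.12). Over the alternatives with the preset correlation its adjusted p ran from 0.016 to 0.13. In oxidative phosphorylation 6 of 38 rose and 0 fell (adjusted p = 0.0013, adjusted p = 0.64 with an estimated correlation), lost with normexp (adjusted p = 0.062, and from 0.00054 to 0.062 over those alternatives) and with a slide 2 median at 0.00. Without proliferating myoblast replicate 1, a setting chosen after the result was seen, 3 rose and 1 fell, with a median of 0.35 (adjusted p = 0.013). Fatty acid genes did not pass as a list: 6 of 22 rose and 5 fell (adjusted p = 0.15).

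Markers of other cell types were measured beside these groups. In collagens and matrix 17 of 32 rose and 6 fell, with 17 and 8 adjusted over the list alone, median 1.87 (adjusted p = 0.0069, adjusted p = 0.53 with an estimated correlation). Col3a1 was 92.5-fold higher and Lama1 at least 337-fold lower. Fibro-adipogenic progenitor and fibroblast genes gave 5 higher and 1 lower of 11 (adjusted p = 0.1), and smooth muscle 5 and 2 of 12 (adjusted p = 0.12). Endothelium gave 3 and 10 of 18 (3 and 12 adjusted over the list alone, adjusted p = 0.12), and tested lower without proliferating myoblast replicate 1 (adjusted p = 0.022, a setting chosen after the result was seen) and without a filter (adjusted p = 0.011), with a range from 0.011 to 0.35 over the alternatives with the preset correlation, and 0.64 with all samples and an estimated correlation. Leukocytes gave 2 and 2 of 15 (adjusted p = 0.9). Adipocytes gave 3 and 3 of 12 (adjusted p = 0.94, median -0.45 under an upward test), Schwann cells and nerve 2 and 5 of 13 (2 and 7 adjusted over the list alone, adjusted p = 0.15) and red blood cells 0 and 2 of 5 (0 and 3 adjusted over the list alone, adjusted p = 0.39). Inflammatory cytokines rose in 10 of 15 cases and fell in 2 (adjusted p = 0.00061, adjusted p = 0.21 with an estimated correlation). Examples were Ccl2 (207-fold) and Csf1 (154-fold). Immediate early genes rose in 7 of 20 and fell in 3 (adjusted p = 0.019, adjusted p = 0.51 with an estimated correlation). The primitive endoderm list (3 higher, 6 lower of 14, with 3 and 7 adjusted over the list alone, adjusted p = 0.1), the interferon list (5 and 9 of 23, adjusted p = 0.52), imprinted genes (8 and 11 of 25, adjusted p = 0.9) and the Notch pathway (4 and 5 of 15, adjusted p = 0.87) did not pass. Without a filter the primitive endoderm and the demethylation list passed (from 0.009 to 0.24 and 0.011 to 0.4 over the alternatives with the preset correlation, and 0.47 and 0.51 with all samples and an estimated correlation). Of the 19 lists past the threshold, 18 had medians of the test's sign on each slide, and 1, the myogenic transcription factors, passed with an estimated correlation.

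Passage 0 myoblasts against stem cells gave 3985 genes higher and 4501 lower of 22413 tested, and 3996 and 4780 with the slide as a block. Of the pluripotency list 29 of 31 genes fell and 0 rose. Among myogenic transcription factors 10 of 14 rose and 1 fell. Myod1 stood at 5.73 ± 0.08, Myog at 6.53 ± 0.26 and Pax7 at 2.87 ± 0.21 in the passage 0 cells. List tests were not run for this comparison or for the steps between days of differentiation, where counts alone are given.

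**Figure D2:**
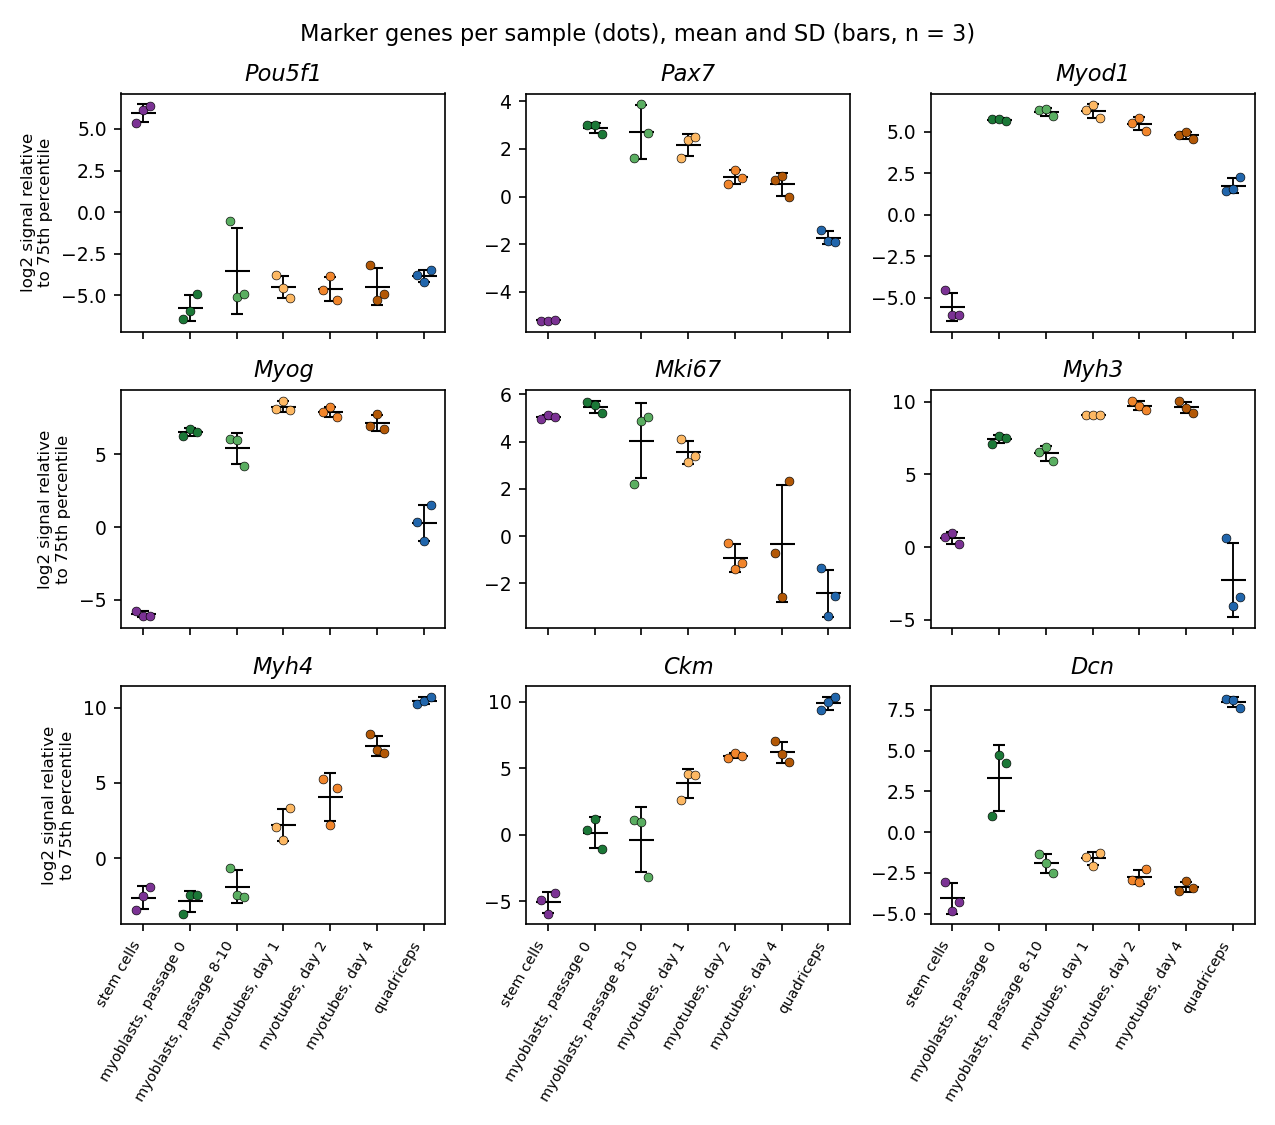
Log2 signal relative to the array's 75th percentile for 9 genes in the 7 groups, with 1 dot per sample and bars for the mean and SD (n = 3). Pou5f1 is high in stem cells alone, Myod1 stands at 6.21 in proliferating myoblasts, Myh3 falls to -2.27 in quadriceps and Dcn reaches 7.99 there.

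Proliferating (passages 8 to 10) and passage 0 myoblasts mostly differ in culture number, so passage cannot be isolated. Matrix-producing cell and leukocyte genes were lower in the former. The proteoglycan gene Dcn fell from 3.33 ± 2.04 to -1.92 ± 0.60 (38-fold, adjusted p = 0.0008), the collagen gene Col1a2 from 5.21 ± 1.66 to 0.76 ± 1.72 (21.8-fold, adjusted p = 0.03), and the leukocyte protease gene Ctss from 1.48 ± 2.27 to below background (at least 37.3-fold, adjusted p = 0.00052). The muscle regulators did not pass: Myod1 was at 6.21 ± 0.24 against 5.73 ± 0.08 (adjusted p = 0.45), Myog at 5.41 ± 1.05 against 6.53 ± 0.26 (adjusted p = 0.24) and Pax7 at 2.72 ± 1.13 against 2.87 ± 0.21 (adjusted p = 0.85). Limma called 123 genes higher and 191 lower of 20353 tested, and 157 and 211 with the slide as a block. With a fit to these 2 groups alone it called 0 higher and 0 lower, where 733 and 880 had an unadjusted p under 0.05 at a fold of at least 2. The share of calls that were higher, 39.2%, became 54.6% with normexp, 24% with quantile normalization and 27.6% with the authors' values. The counts were 29 and 47 without passage 0 replicate 2, and 1377 and 658 without proliferating replicate 3.

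Among genes called, measured on every sample of both groups and without overlap between them, the largest folds upward were those of the glutamate transporter gene Slc1a6 (37.7-fold, adjusted p = 0.00033), the chemokine gene Ccl5 (8.93-fold, adjusted p = 0.049), Gzmd (7.42-fold), Svop (7.42-fold), Ces2g (7.26-fold) and the lipid transfer protein gene Pltp (6.95-fold). Downward among such genes, after Dcn, came the activin subunit gene Inhba (30.7-fold, adjusted p = 0.047), Col1a2, Lrrc32 (18.6-fold), Emilin2 (16.8-fold) and the imprinted Dlk1 (16.5-fold, adjusted p = 0.0039). Every gene named as changed in this comparison lost its call with a fit to the 2 groups alone. Ccl5 and Inhba also lost theirs on leaving out any sample but proliferating replicate 3, and Ccl5 with the slide as a block (adjusted p = 0.05). Over the alternatives their adjusted p ran from 0.025 to 0.26 and from 0.0032 to 0.21. Col1a2 and Lrrc32 lost their calls without passage 0 replicate 2, passage 0 replicate 3 or proliferating replicate 2 (adjusted p from 0.011 to 0.43 and from 0.0072 to 0.42 over the alternatives). Gzmd, Svop and Ces2g lost theirs without passage 0 replicate 1 or 2. Of the genes named below, Mmp3 and Mfap5 lost theirs without passage 0 replicate 2 or 3, and Spry1 without any 1 of the passage 0 samples or proliferating replicate 1. Slc1a6, Pltp, Dcn, Ctss, Emilin2, Dlk1, Lyz1, Pdgfrb, Cspg4, Fabp4 and Hey1 kept theirs on leaving out any 1 sample.

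In collagens and matrix 0 of 38 rose and 6 fell, with 0 and 14 adjusted over the list alone, with a median log2 change of -0.88, -0.76 with lower bounds, and -1.88, -0.62 and -0.90 on slides 1, 2 and 3 (adjusted p = 2.8e-09, adjusted p = 0.21 with an estimated correlation). The stromelysin gene Mmp3 was at least 15.4-fold lower (adjusted p = 0.012). Of the fibro-adipogenic progenitor and fibroblast genes 0 of 15 rose and 4 fell, with 0 and 7 adjusted over the list alone, median -1.78 and -2.45, -0.64 and -1.62 on the slides (adjusted p = 2.4e-05, adjusted p = 0.13 with an estimated correlation). Mfap5 stood at -3.97 ± 2.46 against 0.80 ± 1.64 (27.3-fold, adjusted p = 0.015). Of the leukocyte genes 0 of 25 rose and 7 fell, with 2 and 12 adjusted over the list alone, median -1.87, -1.85 with lower bounds (adjusted p = 1.3e-09, adjusted p = 0.25 with an estimated correlation), and the lysozyme gene Lyz1 fell 135-fold (adjusted p = 0.0065). Slides 2 and 3 gave leukocyte medians of -3.66 and -3.07, but slide 1, with passage 0 replicate 3 and proliferating replicate 1, gave 0.87. Smooth muscle and pericyte genes: 0 of 14 rose and 2 fell, with 0 and 4 adjusted over the list alone, median -0.65 and 0.09, -0.91 and -0.59 on the slides (adjusted p = 0.0022, adjusted p = 0.26 with an estimated correlation). Examples were Pdgfrb (at least 7.5-fold, adjusted p = 0.0028) and Cspg4 (9.37-fold, adjusted p = 0.0065). Adipocyte genes: 0 of 10 rose and 2 fell, with 0 and 3 adjusted over the list alone (adjusted p = 0.022, adjusted p = 0.45 with an estimated correlation), the fatty acid carrier Fabp4 being at least 9.83-fold lower (adjusted p = 0.0065).

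Imprinted genes had a median log2 change of -0.95 and -1.56, 0.12 and -0.46 on the slides (0 of 25 rose and 2 fell, adjusted p = 0.00033, adjusted p = 0.25 with an estimated correlation). Myokines and growth regulators (0 of 18 rose and 1 fell, adjusted p = 0.0023, adjusted p = 0.16 with an estimated correlation) and immediate early genes (0 of 21 rose and 2 fell, with 0 and 3 adjusted over the list alone, adjusted p = 0.0074, adjusted p = 0.47 with an estimated correlation, lost with quantile normalization at adjusted p = 0.064, and from 8.6e-06 to 0.064 over the alternatives with the preset correlation) also tested lower. No member was called in the Z disc list (adjusted p = 0.0084, adjusted p = 0.64 with an estimated correlation), the fusion list (adjusted p = 0.028, adjusted p = 0.47 with an estimated correlation) or the cell cycle exit list (adjusted p = 0.045, adjusted p = 0.44 with an estimated correlation). Adjusted over the list alone, 1 rose and 2 fell in the fusion list, and 1 rose and 2 fell in cell cycle exit. All these list calls were lost with quantile normalization (adjusted p = 0.1, 0.061 and 0.14), and the alternatives with the preset correlation ran from 6.1e-08 to 0.1, 0.0025 to 0.061 and 0.00012 to 0.25. Without proliferating replicate 1, a setting chosen after the result was seen, the Z disc list (median -0.94, adjusted p = 6.1e-08) and the fusion list (adjusted p = 0.046) tested lower, and cell cycle exit did not pass (adjusted p = 0.25). In that setting 7 lists that had not passed with all samples also tested lower, namely adult fast fibre, slow fibre, excitation contraction coupling, endothelium, fatty acid use, pluripotency and inflammatory cytokines (adjusted p from 0.00012 to 0.042). With all samples and an estimated correlation none of these 7 passed (adjusted p from 0.51 to 0.8), and the estimated correlation was not run in that setting. Cell cycle genes, 0 higher and 0 lower of 44, had a median of -0.09 (adjusted p = 0.15, and from 0.0003 to 0.52 over the alternatives with the preset correlation), and Mki67 was at 4.05 ± 1.58 against 5.48 ± 0.25 (adjusted p = 0.36). Myogenic transcription factors had 0 and 0 of 13 called (adjusted p = 0.26). Satellite cell markers had 0 higher and 2 lower, with 1 and 5 adjusted over the list alone (adjusted p = 0.2, and from 0.0053 to 0.86 over those alternatives, median 0.13 under a downward test), the Notch target Hey1 (7.33-fold, adjusted p = 0.00081) and the signalling antagonist Spry1 (2.38-fold, adjusted p = 0.023). None of the 11 lists past the threshold passed with an estimated correlation, and 6 had medians of 1 sign on each slide, not counting adipocytes with -0.18, -0.38 and 0.00.

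Day 4 myotubes against proliferating myoblasts address terminal differentiation. Adult fast myosin and creatine kinase genes came up and the replication programme went down. The fast myosin gene Myh4 rose from -1.91 ± 1.10 in myoblasts to 2.21 ± 1.06, 4.06 ± 1.62 and 7.46 ± 0.68 on days 1, 2 and 4 (day 4: 660-fold, adjusted p = 4.7e-07), and Ckm from -0.37 ± 2.44 to 3.88 ± 1.09, 5.95 ± 0.19 and 6.21 ± 0.80 (95.3-fold, adjusted p = 3.2e-05). Myog was at 5.41 ± 1.05 and then 8.29 ± 0.36, 7.91 ± 0.37 and 7.17 ± 0.56 (3.39-fold, adjusted p = 0.018), while Myod1 went from 6.21 ± 0.24 to 6.25 ± 0.40, 5.49 ± 0.39 and 4.79 ± 0.22 (2.68-fold lower, adjusted p = 0.0071) and Pax7 from 2.72 ± 1.13 to 2.16 ± 0.46, 0.81 ± 0.29 and 0.51 ± 0.47 (4.62-fold lower, adjusted p = 0.00068). The proliferation marker Mki67 was at 4.05 ± 1.58 in myoblasts and 3.54 ± 0.50, -0.94 ± 0.58 and -0.33 ± 2.47 in myotubes (20.8-fold lower on day 4, adjusted p = 0.0013), with day 4 samples from -2.58 to 2.32 that overlapped the myoblasts. Limma called 2618 genes higher and 1843 lower of 17431 tested on day 4, and 2733 and 1951 with the slide as a block. A fit to the 2 groups alone gave 1180 and 902.

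For the other genes with the largest folds among those called, measured on every sample of both groups and without overlap between them, the 4 levels of each gene are for myoblasts and then days 1, 2 and 4, and the fold is for day 4. The transglutaminase gene Tgm2 went from -2.84 ± 1.84 to -0.11 ± 1.35, 2.24 ± 0.75 and 4.45 ± 1.11 (157-fold higher, adjusted p = 7.9e-06). Capn3, a calpain gene of the Z disc list, went from -1.53 ± 2.54 to 2.03 ± 1.73, 4.83 ± 1.38 and 5.41 ± 0.67 (123-fold higher). The prostaglandin synthase gene Ptgds went from -2.65 ± 1.27 to 2.74 ± 0.79, 4.75 ± 0.19 and 4.01 ± 0.67 (101-fold higher). Cmbl went from -2.79 ± 1.81 to -0.67 ± 0.72, 2.29 ± 0.75 and 3.84 ± 1.06 (98.8-fold higher). Among the lower genes the granzyme gene Gzme went from 6.50 ± 0.19 to 1.96 ± 0.16, -2.53 ± 0.72 and -1.0 ± 0.52 (181-fold lower, adjusted p = 5.3e-07). The secretin gene Sct went from 9.80 ± 0.78 to 5.01 ± 0.66, 3.20 ± 0.86 and 2.35 ± 2.05 (175-fold lower). The histone gene H1f5 went from 6.22 ± 1.57 to 3.57 ± 1.12, -0.62 ± 0.93 and 0.23 ± 1.82 (63.2-fold lower). A second histone gene, H2ac4, went from 8.14 ± 1.41 to 5.37 ± 1.20, 1.65 ± 0.76 and 2.53 ± 1.39 (48.7-fold lower). The chemokine gene Cxcl12 went from 5.38 ± 0.77 to 2.79 ± 0.34, -0.53 ± 1.01 and -0.01 ± 1.10 (42.1-fold lower). Mcpt8, a mast cell protease gene, went from 5.65 ± 0.48 to 1.46 ± 0.43, -2.38 ± 1.5 and 0.46 ± 0.47 (36.5-fold lower).

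Of 20 adult fast fibre genes 19 rose and 0 fell, with a median log2 change of 4.15 and 2.76, 5.71 and 3.80 on slides 1, 2 and 3 (adjusted p = 3.6e-14, adjusted p = 0.13 with an estimated correlation). The fast myosin gene Myh2 went from -4.26 ± 1.80 to -3.25 ± 0.49, -1.74 ± 0.60 and 1.74 ± 1.02 (63.9-fold higher, adjusted p = 3.3e-05). Myh1 went from 4.27 ± 0.66 to 6.63 ± 0.55, 7.79 ± 0.55 and 8.56 ± 0.87 (19.6-fold higher). Mybpc2 went from -4.38 ± 3.06 to -3.68 ± 1.34, 0.90 ± 0.79 and 3.31 ± 1.13 (207-fold higher). In the embryonic and neonatal sarcomere list 10 of 15 rose and 0 fell, with 12 and 0 adjusted over the list alone. The median was 3.16 (adjusted p = 1.3e-05, adjusted p = 0.21 with an estimated correlation). Embryonic Myh3 went from 6.45 ± 0.50 to 9.08 ± 0.02, 9.73 ± 0.33 and 9.60 ± 0.40 (8.92-fold higher, adjusted p = 0.0043). Neonatal Myh8 went from 5.64 ± 0.73 to 8.06 ± 0.76, 9.69 ± 0.39 and 10.06 ± 0.68 (21.3-fold higher). Of the slow fibre genes 8 of 14 rose and 1 fell, with a median of 3.60 (adjusted p = 0.00098, adjusted p = 0.47 with an estimated correlation). Mybpc1 went from 1.46 ± 0.76 to 2.72 ± 1.08, 5.08 ± 0.84 and 6.63 ± 0.72 (36-fold higher). Actn2 went from 2.67 ± 1.10 to 5.37 ± 1.04, 7.30 ± 0.13 and 7.56 ± 0.33 (29.6-fold higher). The slow myosin Myh7 was at 4.58 ± 0.66 and then 5.37 ± 0.32, 5.64 ± 0.86 and 6.01 ± 1.52 (adjusted p = 0.64).

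The Z disc list rose in 31 of 32 genes and fell in 0, with a median of 3.88 and 3.00, 4.94 and 3.75 on the slides (adjusted p = 2.0e-18, adjusted p = 0.12 with an estimated correlation). The myotilin gene Myot went from -1.16 ± 1.15 to -0.07 ± 1.01, 1.28 ± 1.09 and 4.82 ± 0.44 (63.3-fold higher). For excitation contraction coupling 23 of 26 rose and 0 fell, median 3.63 (adjusted p = 7.2e-14, adjusted p = 0.13 with an estimated correlation). The calcium store gene Casq1 went from -1.22 ± 2.00 to 0.56 ± 1.28, 3.34 ± 1.05 and 5.09 ± 0.59 (79.5-fold higher). Trdn went from -0.90 ± 0.71 to 2.57 ± 1.45, 4.88 ± 0.43 and 4.60 ± 1.22 (45.1-fold higher). For the neuromuscular junction 9 of 18 rose and 0 fell, median 1.19 (adjusted p = 0.0069, adjusted p = 0.37 with an estimated correlation). Colq went from -0.31 ± 1.19 to 1.22 ± 0.37, 2.35 ± 0.25 and 3.82 ± 0.57 (17.5-fold higher). The adult receptor subunit gene Chrne went from -4.74 ± 1.87 to -5.94 ± 0.76, -4.97 ± 1.32 and -1.28 ± 0.38 (11-fold higher). The fusion list did not pass: 5 of 21 rose and 3 fell (adjusted p = 0.39). The fusogen gene Mymk went from 4.04 ± 1.26 to 7.36 ± 0.64, 8.02 ± 0.29 and 7.56 ± 0.17 (11.4-fold higher). Nfatc2 went from -4.25 ± 0.38 to -1.49 ± 0.98, -0.63 ± 1.08 and 0.97 ± 0.95 (37.3-fold higher).

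Energy metabolism lists all went upward. In glycolysis and glycogen 16 of 26 rose and 1 fell, with 17 and 1 adjusted over the list alone. The median was 1.99 (adjusted p = 6.8e-08, adjusted p = 0.22 with an estimated correlation). Gpd1 went from -1.39 ± 0.66 to 0.15 ± 0.33, 2.25 ± 0.37 and 4.00 ± 0.69 (42.1-fold higher). Ppp1r3a went from -5.36 ± 1.44 to -3.54 ± 1.84, -0.73 ± 1.36 and -0.03 ± 0.89 (at least 13.1-fold higher). In oxidative phosphorylation 25 of 38 rose and 0 fell, median 1.12 (adjusted p = 5.3e-11, adjusted p = 0.32 with an estimated correlation). The mitochondrial creatine kinase gene Ckmt2 went from 0.20 ± 2.41 to 0.16 ± 1.34, 3.72 ± 1.5 and 6.65 ± 0.73 (88-fold higher). Cox7a1 went from 1.95 ± 2.20 to 2.62 ± 0.26, 5.18 ± 0.98 and 7.07 ± 1.0 (34.8-fold higher). In fatty acid use 13 of 24 rose and 0 fell, with 14 and 1 adjusted over the list alone. Here the median was 1.23 (adjusted p = 4.7e-06, adjusted p = 0.25 with an estimated correlation). The transporter gene Cd36 went from -4.66 ± 0.48 to -2.97 ± 1.59, -0.81 ± 1.39 and 0.13 ± 1.12 (at least 14.6-fold higher). Ucp2 went from -2.43 ± 1.63 to -1.80 ± 0.27, -0.11 ± 0.24 and 1.35 ± 0.66 (13.8-fold higher).

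Of 44 cell cycle and DNA replication genes 43 fell and 0 rose (0 higher and 44 lower adjusted over the list alone). Their median log2 change was -3.86, -3.72 with lower bounds, and -4.46, -3.28 and -3.10 on slides 1, 2 and 3 (adjusted p = 2.9e-28, adjusted p = 0.13 with an estimated correlation). Tk1 went from 4.42 ± 0.46 to 2.41 ± 1.28, -1.76 ± 0.55 and -0.24 ± 1.49 (25.3-fold lower). The checkpoint gene Bub1 went from 0.76 ± 0.93 to -0.06 ± 0.70, -5.00 ± 0.52 and -4.18 ± 2.28 (30.6-fold lower). The cell cycle exit list did not pass: 4 of 18 rose and 2 fell, with 5 and 3 adjusted over the list alone (adjusted p = 0.57). Cyclin D1, Ccnd1, went from 6.40 ± 0.13 to 4.76 ± 0.88, 2.02 ± 0.36 and 2.65 ± 0.69 (13.5-fold lower). The inhibitor gene Cdkn1c went from 2.23 ± 0.51 to 8.07 ± 0.88, 8.17 ± 0.81 and 4.85 ± 1.27 (6.14-fold higher, adjusted p = 0.014). Cdkn1c lost its call without day 4 replicate 1 or proliferating replicate 3 (adjusted p from 0.0044 to 0.088 over the alternatives).

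The methylation writers and readers gave 1 higher and 2 lower of 11 (adjusted p = 0.17). Without proliferating replicate 1, a setting chosen after the result was seen, the list tested lower, with 1 higher and 4 lower and a median of -0.58 (adjusted p = 0.0081, and from 0.0081 to 0.19 over the alternatives with the preset correlation). With all samples and an estimated correlation its adjusted p was 0.57, and the estimated correlation was not run without that replicate. Dnmt1 went from 1.41 ± 0.60 to 0.26 ± 0.32, -1.04 ± 0.17 and -0.85 ± 0.46 (4.81-fold lower, adjusted p = 3.4e-05). Uhrf1 went from 4.40 ± 0.40 to 2.58 ± 0.99, -0.95 ± 0.46 and -0.17 ± 1.29 (23.8-fold lower, adjusted p = 3.4e-05). Dnmt3a went from -0.68 ± 0.96 to -0.25 ± 0.61, 0.36 ± 0.66 and 1.65 ± 0.58 (5.06-fold higher, adjusted p = 0.00063). Dnmt3b was at -0.86 ± 0.51 and then -1.38 ± 0.19, -1.41 ± 0.25 and -1.09 ± 0.27 (adjusted p = 0.68). Demethylation and repair genes gave 4 higher and 1 lower of 20 (adjusted p = 0.61). Apobec2 went from -0.27 ± 0.67 to 1.93 ± 0.19, 3.14 ± 0.12 and 3.51 ± 0.56 (13.8-fold higher, adjusted p = 3.2e-06). Tet1 went from -1.97 ± 0.20 to -1.48 ± 0.39, -0.85 ± 0.33 and -0.59 ± 0.52 (2.6-fold higher, adjusted p = 0.01). Tet2 went from -1.73 ± 2.03 to -0.11 ± 0.64, 0.50 ± 0.21 and 0.53 ± 0.77 (4.77-fold higher, adjusted p = 0.02). Tet1 lost its call with a fit to the 2 groups alone and with normexp (adjusted p from 0.0046 to 0.078 over the alternatives). Tet2, whose groups overlapped, lost its call with a fit to the 2 groups alone, with the mean of its probes, and without proliferating replicate 1 or day 4 replicate 2 or 3 (adjusted p from 0.0037 to 0.18 over the alternatives). Tet3 was at -0.82 ± 0.93 and then -1.05 ± 0.21, -0.76 ± 0.25 and -0.65 ± 0.24 (adjusted p = 0.79). Tdg was at -0.87 ± 0.33 and then -0.90 ± 0.32, -0.73 ± 0.21 and -1.24 ± 0.18 (adjusted p = 0.41).

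Myogenic transcription factors went both ways: 5 of 13 rose and 3 fell (adjusted p = 0.54). Mef2c went from -1.31 ± 0.29 to 1.09 ± 1.21, 2.88 ± 0.56 and 3.53 ± 0.44 (28.8-fold higher, adjusted p = 5.1e-06). Myf6 went from -2.17 ± 1.26 to -1.36 ± 1.56, 0.40 ± 2.91 and 1.94 ± 1.76 (17.3-fold higher, adjusted p = 0.01). Without day 4 replicate 1 neither Myf6 (adjusted p from 0.0027 to 0.065 over the alternatives) nor Cd34, described below, passed (from 0.0011 to 0.055). Myog did not pass with a fit to the 2 groups alone or without proliferating replicate 3 or day 4 replicate 2 (adjusted p from 0.0038 to 0.1 over the alternatives). Mki67, Pax7 and Myod1 did not pass with a fit to the 2 groups alone (adjusted p from 3.8e-05 to 0.059, 3.6e-05 to 0.054 and 2e-05 to 0.05 over the alternatives). Satellite cell markers also went both ways: 3 of 16 rose and 8 fell (adjusted p = 0.35). Cd34 went from 3.72 ± 1.60 to 1.20 ± 1.40, -2.65 ± 1.74 and 0.04 ± 1.34 (12.8-fold lower). The Notch target Heyl went from -3.07 ± 1.53 to 1.29 ± 1.02, 0.87 ± 0.36 and 0.41 ± 0.69 (11.2-fold higher). Interferon response genes rose in 16 of 28 cases and fell in 0 (19 higher and 1 lower adjusted over the list alone), with a median of 2.60 and 1.01, 3.23 and 3.25 on the slides (adjusted p = 0.0001, adjusted p = 0.51 with an estimated correlation). Ifit3 went from -3.76 ± 0.56 to -1.44 ± 1.86, -1.76 ± 2.99 and 1.25 ± 1.47 (32.2-fold higher, adjusted p = 0.0026). Usp18 went from -4.28 ± 0.72 to -4.50 ± 0.54, -2.70 ± 2.98 and 0.54 ± 2.19 (28.3-fold higher). Inflammatory cytokines fell in 7 of 14 and rose in 0 (1 higher and 9 lower adjusted over the list alone), with a median of -1.61 (adjusted p = 0.0084, adjusted p = 0.27 with an estimated correlation). Among other cell types, leukocyte genes had 0 higher and 2 lower of 9 (adjusted p = 0.27), and fibro-adipogenic progenitors 3 and 3 of 11 (adjusted p = 0.75). Endothelium had 2 and 3 of 10 (adjusted p = 0.37), and collagens 5 and 3 of 33 (adjusted p = 0.82). All 12 lists past the threshold had medians of the test's sign on each slide, and none passed with an estimated correlation.

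The steps between days address when these changes took place. Day 1 against proliferating myoblasts gave 1258 genes higher and 732 lower of 19127 tested (1328 and 765 with the slide as a block), and 725 and 390 without day 1 replicate 3. Adult fast fibre genes already rose in 10 of 19 cases (13 adjusted over the list alone), and cell cycle genes fell in 15 of 44 (20 adjusted over the list alone). Day 2 against proliferating myoblasts gave 2844 and 1892 of 18323 (2950 and 1948). Day 2 against day 1 gave 176 and 488 of 19019 (202 and 516 with the slide as a block, 59 and 243 with the culture as a block), and cell cycle genes made up 36 of the lower calls, of 40 tested (38 adjusted over the list alone). Day 4 against day 2 gave 58 and 24 of 17753, 67 and 44 with the slide as a block, and 15 and 0 with the culture as a block, where 398 lower genes had an unadjusted p under 0.05 at a fold of at least 2. A fit to those 2 groups alone called 0 and 0, with 562 and 387 at that unadjusted level. Adult fast fibre genes gave 1 higher of 20 in that step (3 adjusted over the list alone), and cell cycle genes 0 higher and 0 lower of 35 (1 higher and 0 lower adjusted over the list alone).

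**Figure D3:**
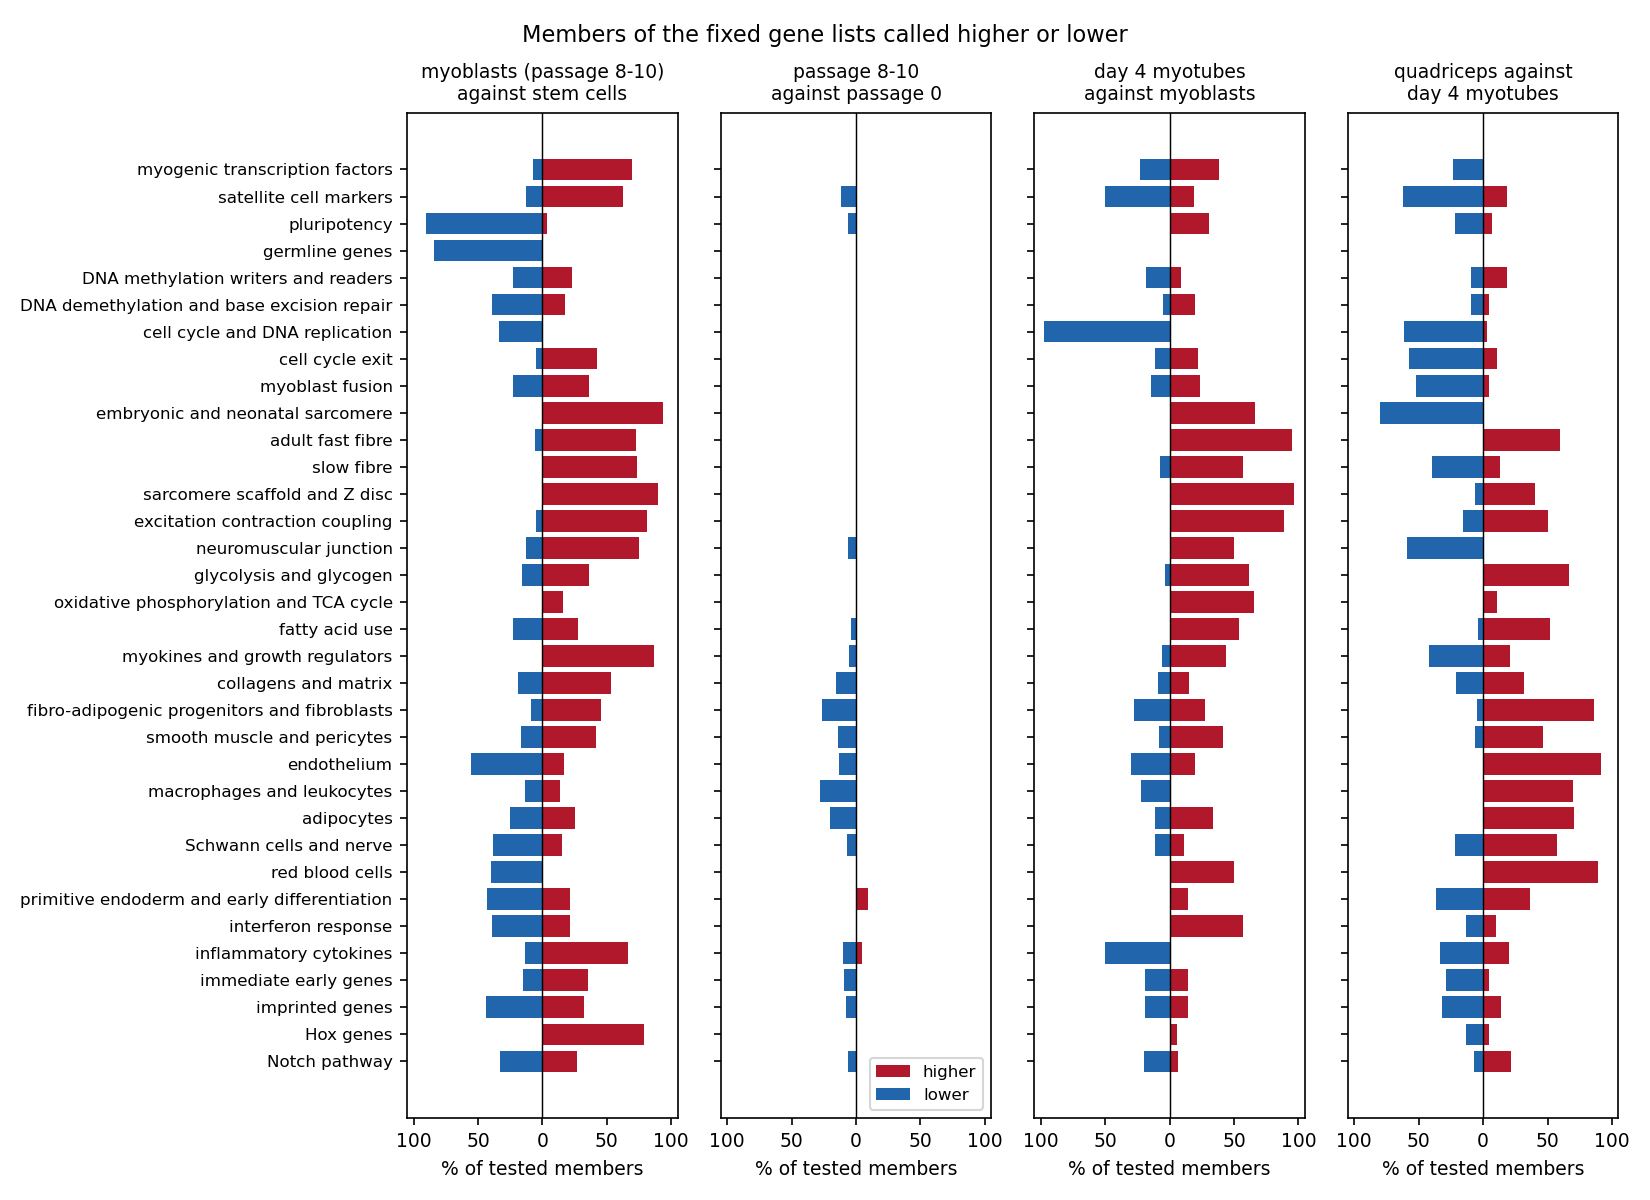
Share of the tested members of each fixed gene list called higher (bars to the right) or lower (to the left) in the 4 main comparisons, in % of members tested. Cell cycle genes reach 43 of 44 lower in day 4 myotubes against myoblasts, and endothelium 22 of 24 higher in quadriceps against day 4 myotubes.

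Quadriceps was compared with day 4 myotubes, from which replicates 2 and 3 differ in strain. Embryonic sarcomere genes were lower in muscle and adult metabolic genes higher, together with markers of blood, vessels, connective tissue and fat. The embryonic myosin Myh3 fell from 9.60 ± 0.40 to -2.27 ± 2.54 (3763-fold, adjusted p = 4.3e-09) and the troponin gene Tnnt2 from 9.41 ± 0.39 to -0.44 ± 1.31 (925-fold, adjusted p = 1.0e-09). The fast myosin gene Myh2 rose from 1.74 ± 1.02 to 8.41 ± 1.52 (102-fold, adjusted p = 5.1e-06), Myh4 from 7.46 ± 0.68 to 10.47 ± 0.23 (8.03-fold, adjusted p = 0.0034) and Ckm from 6.21 ± 0.80 to 9.90 ± 0.48 (12.9-fold, adjusted p = 0.0032). Limma called 2800 genes higher and 3106 lower of 18559 tested, 2930 and 3219 with the slide as a block, and 1508 higher where signal above background was required in both groups. Among genes called, measured on every sample of both groups and without overlap between them, the largest folds upward were those of Clu (255-fold, adjusted p = 4.8e-07), the elongation factor gene Eef1a2 (250-fold), Col1a2 (171-fold), Mlxipl (169-fold), the carbonic anhydrase gene Car3 (154-fold) and the intermediate filament gene Synm (135-fold). Downward among such genes, after Tnnt2, came Myl4 (212-fold, adjusted p = 3.2e-07), Tnni1 (194-fold), Rassf7 (176-fold), Ndrg4 (129-fold) and Dclk1 (128-fold).

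Markers of other cell types stood higher in quadriceps, and the muscle groups are to be read beside them. Endothelial genes rose in 22 of 24 cases and fell in 0, with a median log2 change of 5.27, 4.22 with lower bounds, and 6.23, 4.47 and 5.32 on slides 1, 2 and 3 (adjusted p = 7.3e-17, adjusted p = 0.1 with an estimated correlation). The receptor gene Flt1 stood at 4.28 ± 0.52 (at least 268-fold, adjusted p = 5.4e-09). Red blood cell genes: 8 of 9 rose and 0 fell, median 7.83, 6.24 with lower bounds (adjusted p = 5.2e-08, adjusted p = 0.099 with an estimated correlation), the globin gene Hba-a2 reaching 9.0 ± 0.28 (2378-fold). Fibro-adipogenic progenitor and fibroblast genes: 18 of 21 rose and 1 fell, median 4.99, 4.38 with lower bounds (adjusted p = 1.7e-09, adjusted p = 0.12 with an estimated correlation). Dcn stood at 7.99 ± 0.32 against -3.35 ± 0.30 (2593-fold). Leukocyte genes: 16 of 23 rose and 0 fell, median 4.71, 3.67 with lower bounds (adjusted p = 6.3e-08, adjusted p = 0.29 with an estimated correlation). H2-Eb1 was at least 121-fold higher. Adipocyte genes: 12 of 17 rose and 0 fell, median 4.40, 2.83 with lower bounds (adjusted p = 1.9e-07, adjusted p = 0.21 with an estimated correlation). Fabp4 stood at 6.65 ± 0.43 (at least 1392-fold) and Cfd at 7.16 ± 1.77 (at least 1750-fold). Smooth muscle and pericyte genes: 7 of 15 rose and 1 fell (adjusted p = 0.028, adjusted p = 0.47 with an estimated correlation). Rgs5 was at least 168-fold higher. Schwann cell genes did not pass as a list (8 of 14 rose and 3 fell, adjusted p = 0.12), nor did collagens (12 of 38 rose and 8 fell, with 13 and 8 adjusted over the list alone, adjusted p = 0.25).

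Within the muscle programme the embryonic and neonatal sarcomere list fell in 12 of 15 genes and rose in 0, median -6.28 and -3.83, -6.96 and -6.07 on the slides (adjusted p = 6.3e-08, adjusted p = 0.13 with an estimated correlation). Neonatal Myh8 did not fall: it was at 11.04 ± 0.23 against 10.06 ± 0.68 (adjusted p = 0.11, and from 0.025 to 0.47 over the alternatives), and its second probe, at 67093475 to 67093534 of chromosome 11, was 4.12-fold higher (adjusted p = 0.0096). Probes of the closely related myosin genes were not tested for cross-hybridization. Adult fast fibre genes: 12 of 20 rose and 0 fell, median 2.28 (adjusted p = 3.6e-06, adjusted p = 0.33 with an estimated correlation). Mybpc2 was 66.7-fold higher and Myh1 at 8.5 ± 0.96 against 8.56 ± 0.87 (adjusted p = 0.94). Z disc genes: 13 of 32 rose and 2 fell, median 0.66 (adjusted p = 0.019, adjusted p = 0.64 with an estimated correlation). Examples were Tmod4 (65.4-fold) and Xirp2 (46-fold). Excitation contraction coupling genes: 13 of 26 rose and 4 fell, with 14 and 5 adjusted over the list alone, median 1.44 (adjusted p = 0.015, adjusted p = 0.64 with an estimated correlation), with the chloride channel gene Clcn1 15.1-fold higher and Casq2 38-fold lower. Neuromuscular junction genes fell in 10 of 17 and rose in 0 (adjusted p = 7.8e-06, adjusted p = 0.13 with an estimated correlation), the fetal receptor subunit Chrng being at least 168-fold lower and Chrnd 94-fold lower. Glycolysis and glycogen genes: 18 of 27 rose and 0 fell, median 2.41 (adjusted p = 7.0e-11, adjusted p = 0.14 with an estimated correlation), with Pfkfb1 114-fold and Fbp2 102-fold higher. Fatty acid genes: 13 of 25 rose and 1 fell (adjusted p = 1.2e-05, adjusted p = 0.26 with an estimated correlation). Plin5 was 208-fold higher. Oxidative phosphorylation genes: 4 of 38 rose and 0 fell, with 3 and 0 adjusted over the list alone, median 0.60 and 0.64, -0.03 and 1.14 on the slides (adjusted p = 0.00063, adjusted p = 0.64 with an estimated correlation). Idh3b was 2.99-fold higher.

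Fusion and cell cycle exit genes fell. In the fusion list 1 of 21 rose and 11 fell, median -1.27 (adjusted p = 0.00021, adjusted p = 0.21 with an estimated correlation), with Mymk going from 7.56 ± 0.17 to -2.61 ± 0.80 (1148-fold, adjusted p = 9.8e-10) and Mymx from 6.44 ± 0.57 to -4.67 ± 1.30 (2209-fold, adjusted p = 6.0e-10). In cell cycle exit 2 of 19 rose and 11 fell, with 2 and 13 adjusted over the list alone, median -1.66 (adjusted p = 0.00026, adjusted p = 0.14 with an estimated correlation), the inhibitor gene Cdkn1a going from 8.04 ± 0.36 to 1.23 ± 0.98 (112-fold, adjusted p = 1.2e-08) and Cdkn2a 127-fold lower. Cell cycle genes were lower still in muscle: 1 of 31 rose and 19 fell, with 1 and 20 adjusted over the list alone, median -1.69 and -0.55, -2.59 and -2.67 on the slides (adjusted p = 1.4e-05, adjusted p = 0.52 with an estimated correlation). Mki67 stood at -2.42 ± 1.01 against -0.33 ± 2.47 (adjusted p = 0.08, 0.0072 without day 4 replicate 2, and from 0.0072 to 0.45 over the alternatives). Satellite cell markers: 3 of 16 rose and 10 fell (adjusted p = 0.02, adjusted p = 0.47 with an estimated correlation), Pax7 going from 0.51 ± 0.47 to -1.74 ± 0.27 (4.74-fold, adjusted p = 0.00039) and Ncam1 53.3-fold lower. Myogenic transcription factors had 0 higher and 3 lower of 13, with a median of 0.15 under a downward test (adjusted p = 0.54). Myog was 117-fold lower at 0.30 ± 1.22 (adjusted p = 2.9e-08), Myod1 8.19-fold lower at 1.75 ± 0.46 (adjusted p = 4.7e-06) and Myf6 at 4.48 ± 0.33 against 1.94 ± 1.76 (adjusted p = 0.088). Myf6 was higher past the threshold in 6 of 19 alternatives (adjusted p from 0.019 to 0.33).

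Dnmt3a rose from 1.65 ± 0.58 to 3.48 ± 0.14 (3.54-fold, adjusted p = 0.0034), Uhrf1 fell from -0.17 ± 1.29 to -3.07 ± 1.24 (7.47-fold, adjusted p = 0.0013), and Dnmt1 was at -1.46 ± 0.08 against -0.85 ± 0.46 (adjusted p = 0.14). Tet1 gave no single answer: its brightest probe, at 62276042 to 62276101 of chromosome 10, was 3.52-fold higher in quadriceps (adjusted p = 0.001), its other 2 probes were 2.79-fold and 3.88-fold lower (adjusted p = 0.029 and 0.0039), and their mean changed by -0.54. Tet2, Tet3, Tdg and Apobec2 did not pass (adjusted p = 0.49, 0.29, 0.092 and 0.11). Of the 18 lists past the threshold, 17 had medians of the test's sign on each slide, the exception being oxidative phosphorylation, and none passed with an estimated correlation.

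Slow fibre genes differed among the quadriceps samples. The list gave 2 higher and 6 lower of 15 (2 higher and 7 lower adjusted over the list alone), with a median of -1.62 and 0.33, -2.11 and -1.74 on slides 1, 2 and 3, and did not pass (adjusted p = 0.26, and from 0.04 to 0.35 over the alternatives with the preset correlation). Its median level was highest in quadriceps replicate 1, from a C57BL/6J mouse, and stood at 3.29 and 3.40 in replicates 2 and 3, from 129Sv/C57BL/6J mice. Myh7, the slow myosin, was at 3.98 ± 6.28 in quadriceps (adjusted p = 0.43 against day 4 myotubes, 0.049 without quadriceps replicate 1, and from 0.049 to 0.66 over the alternatives), with 8.92 in replicate 1, 6.10 in replicate 2 and -3.09 in replicate 3. Myl3 was 1103-fold higher than in day 4 myotubes at 7.33 ± 2.64.

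**Figure D4:**
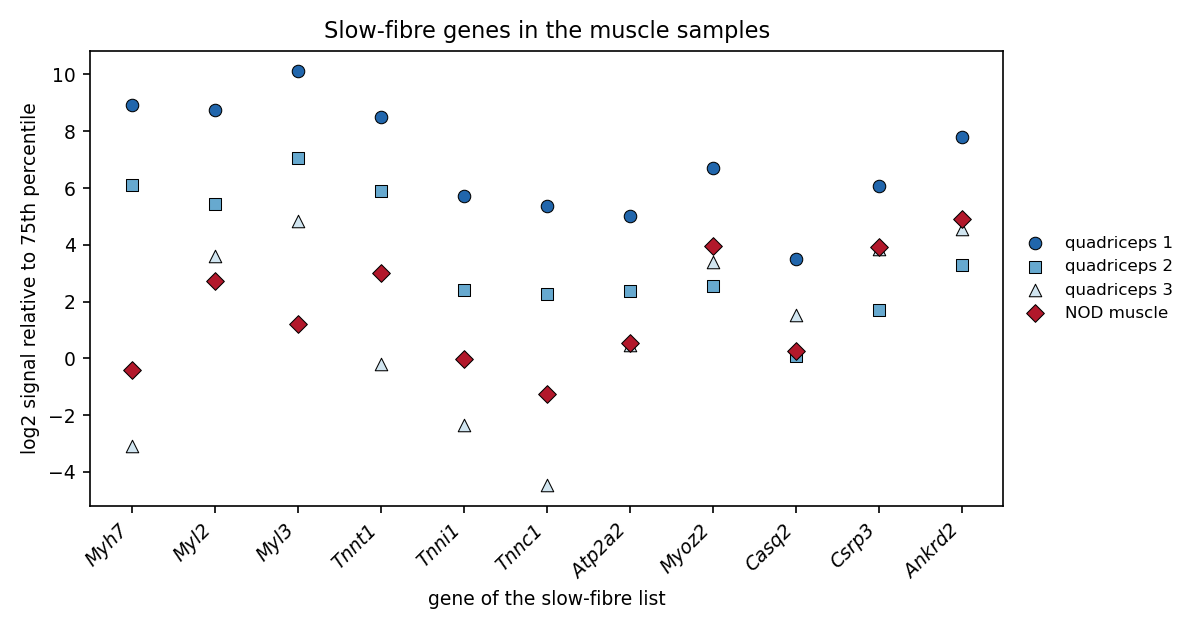
Log2 signal relative to the array's 75th percentile of genes of the slow fibre list in the 3 quadriceps samples and the single NOD muscle sample, with 1 point per sample. Quadriceps replicate 1 is highest for every gene shown among the quadriceps samples, with Myh7 at 8.92 against 6.10 and -3.09.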

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

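Of the tests in this part, those of differentiation, of a swap, of the passage 0 cultures and of the quadriceps samples were chosen only after the result was seen, whereas the test of low signal in proliferating myoblast replicate 1 and the counts over other splits were not.

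The NOD muscle sample, which only an alternative fit used, held a signal above background for 4 genes of the fixed lists that were above background in no quadriceps sample, counting only genes at least 2-fold above the highest of those samples. Other genes were not searched. It exceeded the highest quadriceps sample by 3.00 on the log2 scale for Nefh, 2.93 for Ucp1, 2.81 for Ahsp and 1.62 for Tcl1. It is a single sample, so no test was made.

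Proliferating myoblast replicate 1 stood apart from the other two samples of its group, and its array was the dimmest of 23. The distance to the others, divided by the distance between them, was 3.5, 2.41 and 1.79 in the dimmer bins of genes by mean expression and 1.03 in the brightest bin, which low signal on its array could give. A culture further into differentiation was left undecided: the Z disc list lay 1.25 higher in that sample, at percentile 100 of 10000 random lists matched for expression, while the cell cycle list lay at percentile 6.17 with a median of -0.40. Swapped labels with day 4 replicate 3 are argued against by the adult fast fibre median, 1.73 in this sample against 7.51 and 6.30 in day 4 replicates 1 and 2. A split of the samples points to a structure beyond the groups: proliferating replicate 1 with day 4 replicates 1 and 2 against the rest called 3865 of 19230 genes, 545 of them among the 4461 of the real comparison. The 4 bins, from dimmest to brightest, held 391, 1504, 1167 and 780 of these calls, and the rest lay in no bin. The dimmest bin held 10.2% of the calls in a bin and the 2 dimmer bins 49.3%. The split's first side holds both dimmest arrays, proliferating replicate 1 and day 4 replicate 1, with 75th percentiles of 87.67 and 207.6 units. Those 2 samples also share a culture number and correlated across genes at r = 0.569 after removal of group means. Whether low signal or the culture gave the calls of this split was not tested.

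Leukocyte and fibroblast genes were lower at passages 8 to 10 than at passage 0. Without proliferating replicate 1, 13 genes of both lists were called lower, and 11 with it. This cannot test low signal, as that sample had its group's highest list medians. All 9 leukocyte genes called without it were highest in passage 0 replicate 1, as leukocytes there might give. All 4 fibroblast genes were lowest there, as a different fibroblast share might give. In every passage 0 sample 25 of 29 leukocyte and 15 of 22 fibroblast list members were above background. Effects of passage on the myoblasts themselves were not tested and stay open.

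Slow fibre genes differed between the quadriceps samples. The range over the 3 samples had a median of 4.53, at percentile 100 of the matched random lists, whose percentile 95 was 0.75, which argues against array signal or scaling. The adult fast fibre list had a range of 0.82, at percentile 99.4. All 15 slow fibre genes were highest in replicate 1, as different shares of slow fibres in the muscle taken could give. Strain stays open: the list's median in replicate 1, the only C57BL/6J sample, lay 3.38 above the mean of those in replicates 2 and 3, which share a strain label and stood at 3.29 and 3.40, and with 1 sample of a strain its effect cannot be told apart from that of the animal or the piece of muscle. Gene by gene, replicates 2 and 3 differed by a median of 1.91.

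The 6 samples of each comparison make 10 splits, too few for a share under 0.05, and in each comparison 1 split, the real one, called as many genes as the real one. The real split called 7636 genes and the highest other 4 for proliferating myoblasts against stem cells, 8486 and 1 for passage 0 myoblasts against stem cells, and 314 and 5 for proliferating against passage 0 myoblasts. For quadriceps against day 4 myotubes these were 5906 and 0. Against proliferating myoblasts they were 1990 and 3 on day 1, 4736 and 5 on day 2, and 4461 and 3865 on day 4. They were 664 and 0 for day 2 against day 1 and 82 and 8 for day 4 against day 2. Among splits that part all 3 culture numbers, as the real one does, the highest others were 3, 0, 0, 0 and 0 in the 5 comparisons among proliferating myoblasts and myotubes. Counts of 0 are from limma at an adjusted p under 0.05 and a fold of at least 2, and their unadjusted counts were not computed.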

How the results depend on the processing

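The setting that leaves out both of the dimmest arrays, and the list tests without proliferating replicate 1, were chosen only after the result was seen. In the results that the report names by gene, 1566 of 1589 values under the alternatives stayed on the same side of the threshold for proliferating myoblasts against stem cells, 817 of 972 for proliferating against passage 0 myoblasts, 1434 of 1483 for day 4 myotubes against myoblasts and 1581 of 1613 for quadriceps against day 4 myotubes. Among values past the threshold in either fit, direction turned for Nanog (-4.67) and Tet1 in quadriceps (-0.54) with the mean of a gene's probes, where the probes themselves point apart, and for the oxidative phosphorylation list at passages 8 to 10 with normexp (adjusted p = 0.023), where the cause was not tested. Among gene values that passed in neither fit, direction turned in 2, 27, 2 and 12 cases in these comparisons. The largest of these turns were those of Myh7 in quadriceps (-2.03, and 1.5 without quadriceps replicate 3) and of Ckm at passages 8 to 10 (-0.54, and 0.87 without proliferating replicate 3). The list tests past the threshold numbered 60 of 133, and 1 with an estimated correlation, 57 with quantile normalization, 64 with normexp, 61 with the slide as a block, 64 with a replicate block, 76 of 136 without a filter and 68 of 135 without proliferating replicate 1. For proliferating against passage 0 myoblasts, where 11 passed, quantile normalization lost 4 and added 1, normexp added 6, the missing filter lost 1 and added 12, a replicate block, which does not pair cultures in this comparison, lost 1 and added 3, and leaving out proliferating replicate 1 lost 1 and added 7.

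Counts of called genes that moved by over 1.5 times are given as higher and then lower. The cause was not tested, though in some settings fewer genes or samples entered by construction. With signal required in both groups, fewer genes were tested, and the counts were 1783 lower for proliferating myoblasts against stem cells, 2623 and 2640 for passage 0 myoblasts against stem cells, 54 and 41 for proliferating against passage 0 myoblasts, 312 lower for day 2 against day 1, 27 and 9 for day 4 against day 2, and 1508 higher for quadriceps. Without a filter they were 65 and 319 for day 2 against day 1 and 30 and 5 for day 4 against day 2. With normexp they were 257 higher for proliferating against passage 0 myoblasts and 88 and 47 for day 4 against day 2. The authors' values gave 365 lower in the former and 150 and 71 in the latter, and quantile normalization 393 lower in the former.

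The replicate block pairs cultures only among proliferating myoblasts and myotubes, and in the other comparisons it joins samples with different culture labels. With it limma called 2138 higher for proliferating myoblasts against stem cells, 0 and 0 for proliferating against passage 0 myoblasts (776 and 930 at an unadjusted p under 0.05 and at least 2-fold), 59 and 243 for day 2 against day 1, and 15 and 0 for day 4 against day 2 (398 lower at the unadjusted level). With the slide as a block 44 fell in day 4 against day 2, and with an intensity trend 52. A fit to the 2 groups alone, on fewer samples, called 0 and 0 for proliferating against passage 0 myoblasts (733 and 880 unadjusted) and 0 and 0 for day 4 against day 2 (562 and 387 unadjusted). Against proliferating myoblasts it called 264 and 119 on day 1, 1635 higher on day 2, and 1180 and 902 on day 4. Treat, which asks for a larger change by construction, called 13 and 63 for proliferating against passage 0 myoblasts, 497 and 195, 1500 and 1166, and 1431 and 1035 for days 1, 2 and 4 against proliferating myoblasts, 17 and 182 for day 2 against day 1, 16 and 1 for day 4 against day 2, and 1841 and 2028 for quadriceps.

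Leaving out 1 sample at a time gave 29 to 1377 higher and 47 to 658 lower for proliferating against passage 0 myoblasts, lowest without passage 0 replicate 2 and highest without proliferating replicate 3, and 303 lower without both of the dimmest arrays. For day 1 against proliferating myoblasts the ranges were 725 to 1432 and 390 to 931, lowest without day 1 replicate 3. For day 2 against day 1 they were 33 to 210 and 234 to 535, lowest without day 1 replicates 1 and 2. For day 4 against day 2 they were 19 to 60 and 4 to 28, lowest without day 4 replicate 1 and day 2 replicate 3. Of called genes with several probes, a probe was called in the opposite direction in 27 of 2522, 0 of 97, 9 of 1503 and 17 of 1949 in the main comparisons. Signal over background limits what can be measured, since only 39.1% to 60.1% of spots on an array were well above it.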

Other observations

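All values in this part were chosen only after the result was seen. The NOD muscle sample correlated with the mean of the quadriceps samples at r = 0.983 across 23426 genes, which are not independent replicates, with day 4 myotubes at 0.882 and with stem cells at 0.702. Genes of the lists were counted only where this sample lay outside the range of the quadriceps samples and at least 2-fold from their mean. By that count 10 of 31 interferon response genes lay below and 0 above. The median difference over all 31 was -0.81 on the log2 scale. By the same count 7 of 18 adipocyte genes lay below and 1 above, and 5 of 26 leukocyte genes below and 1 above. These are counts from a single sample and no test was made.

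By the same count 2 of 15 slow fibre genes lay below and 0 above. The median difference from the quadriceps mean, a mean raised by quadriceps replicate 1, was -1.59, and that of Myl3 was -6.13. H2-Aa, a gene of antigen presentation, differed by -5.77, and the fusogen gene Mymx by 4.92. Gadd45g and the cell cycle inhibitor gene Cdkn1a stood higher by 2.64 and 2.01. The labels do not say which skeletal muscle was taken from the NOD mouse.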
